A study of Glycine max with 4 samples.

How the data were processed

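RNA from shoot (meristem) tips of soybean, Glycine max cultivar Thorne, was sequenced in 4 libraries, each from 1 plant. The comparison was between groups, as the series' design text does it: 2 tagged plants, which carried the mmPing20F activation tag at chromosome 8 position 2785626, and 2 untagged plants. Untagged replicate 1 was a transgenic plant with the transposase construct, and untagged replicate 2 was untransformed. The design text and the sample labels spell the name of the transgenic untagged plant differently, by 1 digit, and they were taken as the same plant. The genome build of that position, the annotation and the strand setting of the counting are not given in the sources used here. Per the submitters' processing notes, CASAVA 1.8, HISAT2 2.1.0, HTSeq 0.6.1 and DESeq2 were used.

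Both files analysed are tables of the whole series over 56044 genes. The first holds the authors' raw read counts per gene, whole numbers that summed to between 27900266 and 49210060 per library. The second, deposited by the authors, holds a scaled signal: each count divided by 1 size factor per library. Multiplying the deposited values by the 4 factors (1.48, 0.839, 0.942 and 0.852 for tagged 1, tagged 2, untagged 1 and untagged 2) gave whole numbers within 0.01 for 100% of values, and the factors equalled the median-of-ratios size factors recomputed from the counts. These values are called normalized counts below. That table also holds a single linear fold ratio, in the row of Glyma.08G035100 and under no column name; the authors' deposited value, 4.09, equalled the DESeq2 fold change of tagged over untagged plants recomputed here. No other fold change or p-value of the authors was used. Every row carried a gene identifier, 8248 genes had 0 counts in all 4 libraries, and no column of per-sample values was left unused.

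Gene identifiers of the form Glyma.08G035000 are used as the files give them. In this naming the digits before the G are the chromosome and the number after it rises along the chromosome. The files do not pair identifiers with gene names. The reference table at hand, 59048 RefSeq genes of another soybean assembly, holds 0 of these identifiers, so no gene could be named and no coordinates are given. For that reason 28 lists of genes by function and tissue (photosynthesis, hormones, defence, transposons, silencing, and markers of root and nodule, seed, and pollen and anther among them) were fixed before the data were examined but were not tested. The number of identifiers printed was limited for the same reason. The rule for naming genes given below is therefore narrower than the planned one. The planned rule took more genes per direction and the nearest genes on each side of the insertion.

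The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the raw counts of all 4 libraries, with group as the only term, TMM scaling, edgeR's default filter on low counts by group (38824 genes kept), and Benjamini-Hochberg adjustment at 0.05. Standard errors of log2 fold changes were computed as the absolute change divided by the square root of the test's F. The position of the insertion among the identifiers was not known. The gene marked in the authors' table therefore stood for it, with the 10 identifiers on each side (21 genes), a choice made after the files were seen; p-values of the tested neighbours were also adjusted over the list alone. Because the authors marked that gene on these samples, this adjustment is not independent evidence. The rule for naming genes took the genes with the smallest p in each direction, at most 2 per direction, the marked gene, and neighbours past the threshold over the list alone; the 4 genes called without the untransformed plant, and the on and off genes of the closing section, were named after their values were seen. Pairs of libraries were compared on log2(normalized count + 1) over genes with a pair mean of at least 50, with exact Clopper-Pearson 95% intervals for shares, which cover counting error over genes only.

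Alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), RLE and upper-quartile scaling, 2 other filters, a robust fit, a 2-fold minimum, transgenic status as a covariate, the replicate number as a block, and leaving out each library in turn. The correlation of deviations between same-numbered libraries was -0.052 over 38824 genes. This check could hardly detect pairing, because the untagged deviation holds the large difference between the transgenic and the untransformed plant. The numbers were not treated as pairs in the main test. Chi-square per degree of freedom between libraries was at least 17.6, above counting error, so no library was a repeat sequencing run of another. A second preparation of one sample cannot be told from this value.

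The tests were tested on simulated data with 200 changed genes of at least 100 mean counts. In a simulation of all 4 libraries (38824 genes), 0% of genes changed 2-fold, 0% of those changed 4-fold, 28% of those changed 8-fold and 86% of those changed 16-fold were called, and 3 unchanged genes were called. Apart from the planted changes, it gave every library a common level and an equal spread per gene. In the data the untransformed library stood apart from the other 3, so these shares do not measure the power of the test there. In a simulation of the 3 transgenic libraries (39528 genes), 74% of 2-fold and 98% of 4-fold changes were called, together with 50 unchanged genes, more than the adjustment allows for. Apart from the planted changes, it too gave every library a common level and an equal spread per gene. How strict the adjustment is also depends on the number of changed genes, here 200 planted ones. These shares therefore do not measure the power of the test in the data either.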

Results

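Gene expression in soybean shoot tips was measured by RNA sequencing in 4 plants grown for 1 month, from tips of 5 cm that included immature trifoliate leaves. mPing is a small transposable element of rice that moves when its transposase is supplied. The mmPing20F element is an mPing-based activation tag, designed so that an insertion raises the expression of genes beside it. Plants of cultivar Thorne carried the tag at chromosome 8 position 2785626 (tagged 1 and 2, n = 2). The plants without it (untagged, n = 2) were a transgenic plant with the transposase construct (untagged 1) and an untransformed Thorne plant (untagged 2). Library totals were 49210060 and 27900266 counts for the tagged plants, 30958755 for the transgenic untagged plant and 34186179 for the untransformed plant. Between 44347 and 45526 genes had at least 1 count per library. The 10 most abundant genes took between 2.58% and 3.73% of the counts.

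The library of the untransformed plant was unlike those of the other 3 plants, and the 2 untagged plants were the most different pair of all. Of 33006 genes with a mean of at least 50 normalized counts, 12376 (37.5%, 95% interval 37.0 to 38.0) differed by over 2-fold between the 2 untagged plants. Of these, 6586 genes were higher in the untransformed plant and 5790 in the transgenic one. At over 8-fold, 1511 genes were higher in the untransformed plant and 308 in the transgenic plant. The untransformed plant differed from tagged 1 and tagged 2 by over 2-fold at 34.4% and 36.5% of genes. The transgenic untagged plant differed from the same tagged plants at 1.86% (1.72 to 2.01) and 3.23% (3.04 to 3.43) of genes, and the tagged plants differed from each other at 1.58% (1.44 to 1.72). Spearman's rho across genes was 0.984 between the tagged plants, 0.981 and 0.974 between them and the transgenic untagged plant, and at most 0.786 in the pairs with the untransformed plant; genes are not independent replicates. The comparison of the 2 untagged plants has 1 library on each side and no replicate check.

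**Figure D1:**
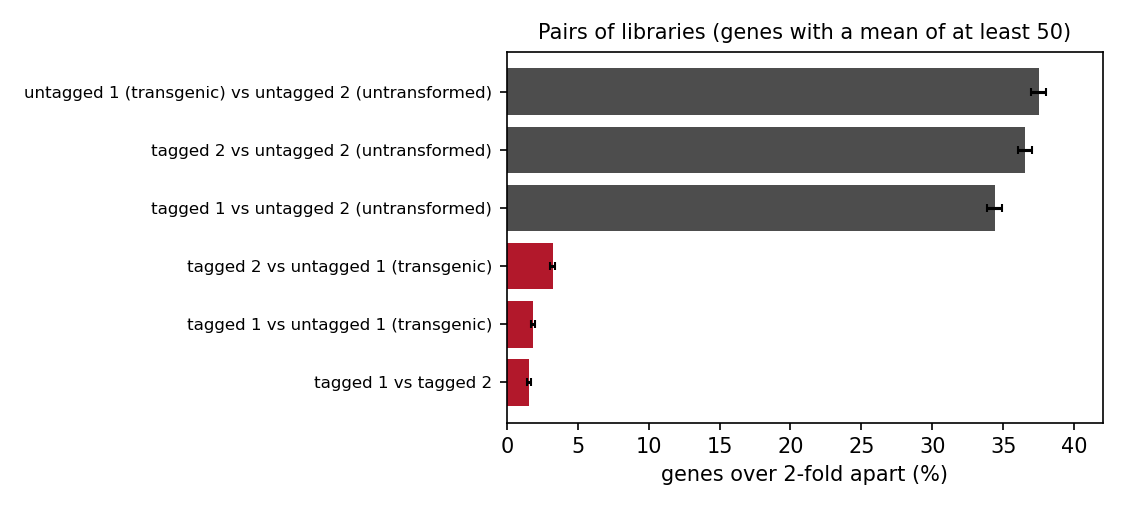
The bars give the percentage of genes over 2-fold apart (x axis, %) for each of the 6 pairs of libraries, over genes with a pair mean of at least 50 normalized counts, and the whiskers are exact 95% intervals. The 3 grey pairs with the untransformed plant lie between 34.4% and 37.5%, and the 3 red pairs without it lie between 1.58% and 3.23%.

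The study's central comparison asked which genes differed between plants with and without the tag. The genes that separated the groups most clearly were Glyma.15G000100 and Glyma.08G035000, both higher in the tagged plants. Over all genes and all 4 libraries both passed in DESeq2 and neither passed in edgeR's test, the main one here. Glyma.15G000100, the first-numbered gene of chromosome 15, had 376 ± 15.2 normalized counts in tagged plants (SD, n = 2) against 1.06 ± 1.5 in untagged plants. Its raw counts were 541 and 324 in the tagged libraries and 2 and 0 in the untagged libraries, a scaled ratio of 334 with a counting interval of 92.2 to 2760. Glyma.08G035000, on the chromosome of the insertion, had 1529 ± 6.13 normalized counts in tagged plants against 247 ± 62.6 in untagged plants, a 6.19-fold difference. Its level was 203 in the transgenic untagged plant and 291 in the untransformed plant. In the other direction the smallest p-values belonged to Glyma.02G118400, at 9.05 ± 4.37 in tagged and 69.7 ± 16 in untagged plants, and Glyma.03G121400, at 1.95 ± 1.06 and 57.9 ± 48.7.

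With edgeR's quasi-likelihood test, 0 of 38824 genes were higher and 0 were lower in tagged plants at an adjusted p of 0.05, and the smallest adjusted p was 0.947. Unadjusted, 444 genes had p under 0.05, 364 of them higher and 80 lower in tagged plants, where 1941 would be expected by chance. This balance depended on the tool and the filter: at the same unadjusted limit DESeq2 gave 356 higher and 1682 lower genes, and edgeR without the low-count filter gave 345 and 236. Log2 fold changes were 8.26 ± 0.92 (SE) for Glyma.15G000100, with an unadjusted p of 5.7e-04 from edgeR, and 2.63 ± 0.31 for Glyma.08G035000, with an unadjusted p of 7.6e-04 from edgeR. They were -2.89 ± 0.61 for Glyma.02G118400 and -4.72 ± 1.03 for Glyma.03G121400, with an adjusted p of 0.947 for all 4 of these genes. Leaving out 1 library at a time moved these values: Glyma.15G000100 ran from 7.40 to 11.64, Glyma.08G035000 from 2.42 to 2.92, Glyma.02G118400 from -3.51 to -2.49 and Glyma.03G121400 from -5.44 to -3.38. The 11.64 is a fitted value against the untransformed library alone, where Glyma.15G000100 had 0 counts, so no ratio exists there without edgeR's prior count. DESeq2 called 6 genes higher, Glyma.15G000100 (DESeq2 adjusted p = 2.3e-08) and Glyma.08G035000 (DESeq2 adjusted p = 2.0e-04) among them, and 27 lower; among the 27 lower genes, 27 were over 10 times higher in the untransformed plant than in any of the other 3 plants. The count of 0 rested on the untransformed plant: without it the test called 4 genes, and with it as the only untagged plant (without untagged 1) it called 9669 genes higher and 10419 lower. The biological coefficient of variation was 0.457 with all 4 libraries and 0.147 without the untransformed one.

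Among the 3 transgenic plants, which share the transgenic background by their labels, the tagged plants were compared with a single untagged plant. A difference can therefore belong to that plant rather than to the tag. Glyma.15G000100 (log2 fold change 7.40 ± 0.40, adjusted p = 0.0168) and Glyma.08G035000 (2.92 ± 0.17, adjusted p = 0.0168), tested with edgeR's quasi-likelihood test, rose in both tagged plants. Glyma.12G015100 fell from 714 normalized counts in the transgenic untagged plant to 103 ± 8.89 in tagged plants, a log2 fold change of -2.79 ± 0.18 with an edgeR adjusted p of 0.0259. Glyma.11G152700 fell from 444 to 34.2 ± 7.32, a log2 fold change of -3.71 ± 0.27 with an edgeR adjusted p of 0.042. Both of these genes were lower still in the untransformed plant, at 16.4 and 17.6 normalized counts, so their direction turned when that plant was the control. The 2 genes that rose were higher in both tagged plants than in either untagged plant.

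This second comparison has a single untagged library, which is assumed to vary like the tagged pair, and 39528 genes were tested. In simulated data of this design 50 unchanged genes were called beside the changed ones, so its calls are less certain than their adjusted p. Unadjusted, 3746 genes had p under 0.05 in edgeR, 2333 of them higher and 1413 lower. DESeq2 on the same 3 libraries called 211 genes higher and 23 lower, including the 4 edgeR genes, while limma-voom called 0 genes, with 3336 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0572. A fit of all 4 libraries with transgenic status as a covariate is no separate evidence, since the covariate takes up the only untransformed library and the tag is then estimated from these same 3. It called 2 of the 4 genes, Glyma.15G000100 and Glyma.08G035000, each with an edgeR adjusted p of 0.0311.

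**Figure D2:**
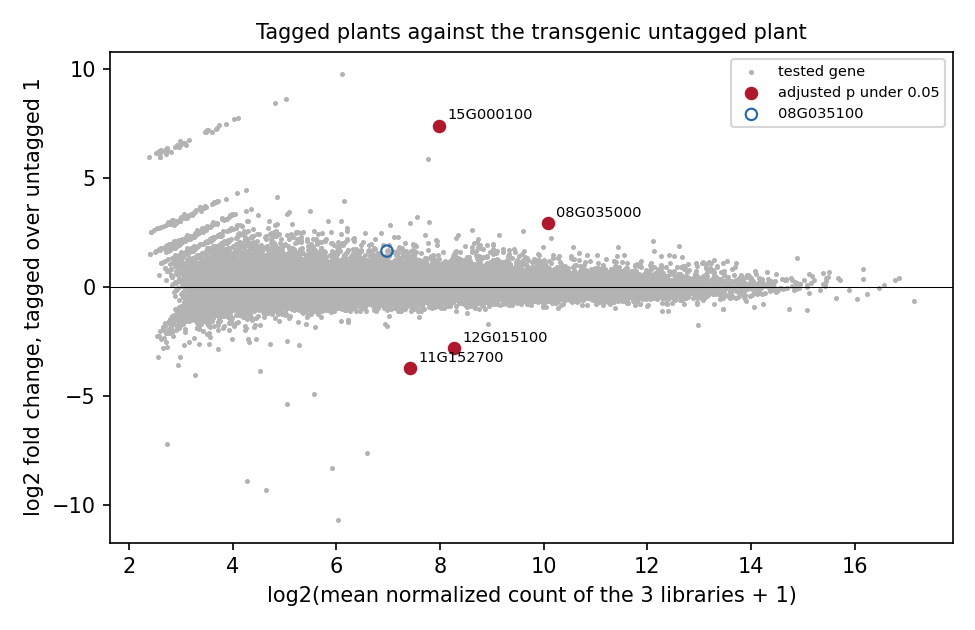
Each grey point is 1 of 39528 tested genes, with the log2 mean normalized count of the 3 transgenic libraries on the x axis and the log2 fold change of tagged plants over the transgenic untagged plant on the y axis. Red points are the 4 genes past an adjusted p of 0.05, with Glyma.15G000100 at 7.40 and Glyma.08G035000 at 2.92 above 0, and the open circle is Glyma.08G035100 at 1.65.

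The position of the tag among the identifiers was not known. The stretch of chromosome 8 around Glyma.08G035100, the gene for which the authors deposited a fold change of 4.09, stood for its neighbourhood. Glyma.08G035100 and the gene numbered just before it, Glyma.08G035000, were both higher in the 2 tagged plants than in either untagged plant. This order was not particular to the pair: it held at 6 of the 16 tested genes of the stretch, and the reverse at 0. How often this order holds over all tested genes was not computed, so it is not read as a rise across the stretch. Glyma.08G035100 had 162 ± 32.9 normalized counts in tagged and 39.5 ± 17.7 in untagged plants (SD, n = 2), with 52.0 in the transgenic and 27.0 in the untransformed plant. It was 3.11-fold above the transgenic untagged plant, and Glyma.08G035000 was 7.54-fold above it. The next gene on the other side, Glyma.08G035200, differed little, at 866 and 823 in tagged and 720 and 1022 in untagged plants. The gene numbered before the pair, Glyma.08G034900, was at 56.0 and 54.8 against 42.5 and 24.7.

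Of the 21 genes in this stretch, 16 could be tested and 2 had 0 counts in every library. Over all genes, 0 neighbours passed in edgeR's test and 1 neighbour, Glyma.08G035000, passed in DESeq2. Glyma.08G035100 had a DESeq2 adjusted p of 0.274 over all genes. Adjusted over the list alone, 1 neighbour passed: Glyma.08G035000 rose, with an edgeR adjusted p of 0.0122. Glyma.08G035100 had a log2 fold change of 2.03 ± 0.52 and an adjusted p of 0.123 over the list alone, and the other 14 tested neighbours ranged from -2.01 to 1.23 with a median of -0.018. Without the untransformed plant, a single untagged library is left. There the log2 fold changes were 2.92 ± 0.17 for Glyma.08G035000 and 1.65 ± 0.34 for Glyma.08G035100. The other 14 neighbours tested there ranged from -0.885 to 0.984, with Glyma.08G035300 at 0.61 ± 0.16. They are not the same 14 as with all 4 libraries. Glyma.08G036100, the lowest with all 4 at -2.01, was not tested here. Glyma.08G035600, the lowest here at -0.885, was not tested with all 4. Glyma.08G035300 was at 1803 normalized counts in the untransformed plant, above both tagged plants at 686 and 753, so its direction depends on the control. The number of neighbours past the threshold depended on which library was left out. The number over all genes did so too, so it is not read as an effect particular to this stretch. With the untransformed plant as the only control, the log2 fold changes were 2.42 for Glyma.08G035000 and 2.61 for Glyma.08G035100. The other neighbours tested there ranged from -2.97 to 1.58.

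**Figure D3:**
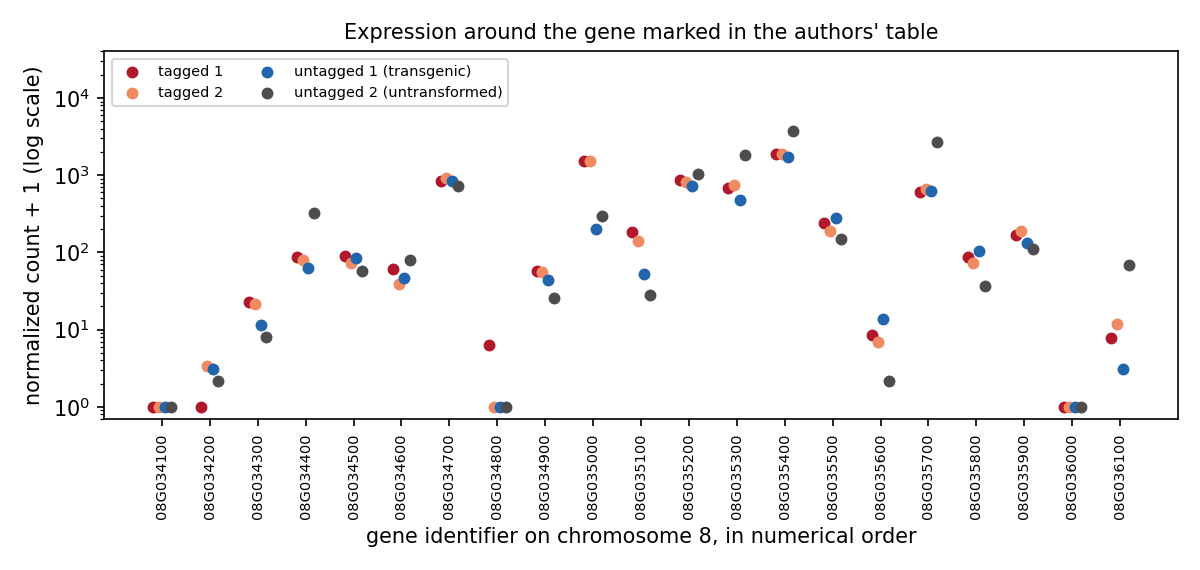
Normalized counts plus 1 (y axis, log scale) are shown for the 21 genes numbered Glyma.08G034100 to Glyma.08G036100 (x axis, in numerical order), with 1 point per library and colour for the plant. Both tagged plants lie above both untagged plants at Glyma.08G035000 (1533 and 1525 against 203 and 291) and at Glyma.08G035100 (185 and 138 against 52.0 and 27.0), 2 of the 6 tested genes with that order.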

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

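The counts of 0 genes higher and 0 lower in tagged plants held under RLE and upper-quartile scaling and both other filters. They also held under limma-voom, the robust fit, the 2-fold minimum and the replicate block (0 and 0 genes, 1 neighbour). DESeq2 gave 6 higher and 27 lower genes. In the stretch around Glyma.08G035100 it gave 2 neighbours past the threshold over the list alone, 1 of them over all genes. Transgenic status as a covariate, which leaves the tag estimated from the 3 transgenic libraries, gave 2 higher genes and 3 neighbours. Leaving out 1 library gave 0 to 9669 higher genes, 0 to 10419 lower genes and 0 to 8 neighbours; the upper ends came from leaving out untagged replicate 1, which leaves the untransformed plant as the only control. Leaving out untagged replicate 2 and using DESeq2 gave 211 higher genes, 23 lower genes and 2 neighbours, and with limma-voom 3 neighbours; these combined settings and limma-voom with quality weights, which gave 0 genes, were chosen after seeing the data. Over the same left-out libraries the log2 fold change of Glyma.11G152700 ran from -3.71 to 0.96 and that of Glyma.12G015100 from -2.79 to 2.66, with the sign turned when the untransformed plant was the only control. The share of genes over 2-fold apart between the untagged plants was 40.4% at a mean of at least 10 and 34.3% at a mean of at least 200, both limits chosen after seeing the data. The gene list alternatives were not run, since no gene could be named. With 2 plants per group there are 3 splits of the libraries, too few for a share under 0.05: the real split called 0 genes, with 444 at an unadjusted p under 0.05, and the others 0 genes each, with 588 and 723. The cause of the other changes was not tested.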

Other observations

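The tests of thinning, of removed genes, of an adjacent pair in random gene orders and of shared counts were set out before their results were seen. The others, including that of neighbouring genes moving together among the transgenic plants, were chosen after. Among the 3 transgenic plants, 5 genes had at least 50 normalized counts in the untagged plant and at most 3 in both tagged plants. Among them was Glyma.03G121400, described above, which also had 20 raw counts in the untransformed plant; the other 4 had 0 there. Of those 4, 3 carry consecutive numbers on chromosome 13, Glyma.13G086600 to Glyma.13G086800, with raw counts of 68, 166 and 52 in the untagged transgenic plant, of 0, 0 and 0 in tagged 1 and the untransformed plant, and of 0, 1 and 0 in tagged 2. Glyma.10G079500 had 182 counts in the untagged transgenic plant and 0 in the other 3 plants. In the opposite direction 2 genes were on in both tagged plants and off in the transgenic untagged plant, Glyma.15G000100 and Glyma.18G183500 (72.8 and 131 normalized counts against 0, and 4.70 in the untransformed plant). These 7 genes were singled out after their values were seen. Between the tagged plants, 5 genes were on in tagged 1 and off in tagged 2, and 1 gene the reverse.

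Among the 3 transgenic plants, genes next to each other in the order of tested genes moved together more often than in random orders. Of 1082 genes with an unadjusted p under 0.01, 53 adjacent pairs changed in the same direction, against a mean of 18.3 and a highest value of 35 in 1000 random gene orders (permutation p = 0.001, the smallest these orders can give).

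The first pattern is the distance of the untransformed library from the other 3. Depth did not account for it: with all libraries thinned to 27900266 counts, 37.0% of genes were still over 2-fold apart between the untagged plants, against 1.48% between the tagged plants. Removing the 194 genes that were among the 100 most abundant of any library left 37.3%. Transgene status, line, growth stage, the tissue sampled or mixed in, or the preparation of that plant cannot be told apart, because there is only 1 untransformed library and no gene could be named for a test of tissue markers.

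The second pattern is the rise of both Glyma.08G035000 and Glyma.08G035100, on the chromosome of the tag. The untransformed library did not account for it, since the log2 fold change of Glyma.08G035100 was 1.65 without that library. In random gene orders an adjacent pair as extreme appeared in 0.5% of orders. The limits of that test were the p-values of this pair, which had already been seen. The authors had also marked 1 of its genes on these samples, so the share is not independent evidence. Neighbouring tested genes also moved together more often than in random orders, so random order is a lenient standard. Transcripts of one gene counted in the other stay open. The gain of Glyma.08G035100 was 9.52% of that of Glyma.08G035000. That share lay close to the lowest ratio between these genes in any library, 9.07% (7.43 to 11, counting error only). The lowest ratio was that of tagged 2, whose level is mostly the gain, so the comparison cannot decide. The ratio was 12% in tagged 1, 25.7% (18.3 to 35.3) in the transgenic untagged plant and 9.27% (5.77 to 14.2) in the untransformed plant. A candidate explanation is an effect of the tag on both genes; a difference between the plant lines at this locus was not tested and is an alternative, since both tagged plants carry the same insertion.

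The third pattern is Glyma.15G000100, on another chromosome than the tag. The next 10 tested genes had a median absolute log2 fold change of 0.151 among the transgenic plants (highest 1.39). This argues against a changed chromosome segment that moves the expression of most of them. A changed segment that leaves their levels as they are would not be seen. A shorter segment stays open, since a few changed genes would not move the median. Only the genes on a single side could be examined, because Glyma.15G000100 is the first-numbered gene of its chromosome. On and off genes that differ between plants of equal tag status exist, with 6 genes on in one tagged plant and off in the other, but whether Glyma.15G000100 is one cannot be told apart from a difference with the tag, because there is only 1 transgenic untagged plant. Another insertion of the tag near it was not tested and stays open, as does any other difference between the lines.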
